A study of Homo sapiens with 12 samples.

How the data were processed

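Gene expression was measured in NGP cells, a human neuroblastoma line, on Illumina bead arrays. There were 12 arrays in 3 groups of 4. The groups were DMSO, RG7388 at 75 nM, and RG7388 at 75 nM with GSK2830371 at 2.5 µM, each for 4 h. Groups and repeat numbers were taken from the sample labels, and the labels' protocols describe 4 independent biological repeats. No array of GSK2830371 alone was analysed here.

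The deposited table of non-normalized values holds bead signal intensity on a linear scale and a detection p-value per probe, per the file headers. The scanner software is not given in the sources used here. A second deposited table holds values on a log2-like scale that the authors normalized, with lumi named in the submitters' processing notes and no version or transform stated. Compared with the log2 of the signal, these values rise less steeply near the background, so that fold changes of dim genes are smaller on that scale. The authors' deposited log2 values were used as an alternative and the signal intensity as the main source. The value table of the series equals the authors' normalized table and was not used here.

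The signal was background-corrected and quantile-normalized with neqc in limma 3.58.1 (R 4.3.3), which estimates the background from the detection p-values, with an offset of 16. Of 47320 probes, 30113 had 1 gene symbol in the platform annotation, 8 had several and 17199 had none here. A separate table of gene IDs and symbols held 30074 of the 30113 by gene ID, and changed 0 symbols. Probes with a detection p under 0.01 on at least 4 of the 12 arrays were kept, which left 16030. Of these, 12891 had 1 symbol, and the probe with the highest mean over the 12 arrays stood for its gene, which gave 9882 genes. No genome build is named in the sources used here, so no coordinates are given. The detection p moves in steps of 1 in 770.

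Each gene was fitted with lmFit and eBayes in limma over all 12 arrays with the group as the only term, and the 3 comparisons were drawn from that fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons, the gene lists, the rule for named genes and, apart from those said below to be later, the other settings were fixed before the data were examined. Of the 22 lists, 6 held p53 targets (cell cycle arrest, apoptosis and death receptors, DNA repair, negative feedback, metabolism and redox defence, and others). The rest held G1/S and E2F targets, G2/M genes, MYC and MYCN targets, adrenergic and mesenchymal identity genes, leukocyte and epithelial markers, NF-kB targets, interferon response genes, the ATF4 and unfolded protein response, heat shock, immediate early, xenobiotic response and hypoxia genes, cholesterol synthesis and ribosomal proteins. Some lists share members. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists of a comparison, and again with an estimated correlation and with fry. fry tests whether a list's genes move one way on balance, without comparing them with other genes. The number of arrays limits the precision. In 20 simulations with 200 changed genes among 9882, drawn for RG7388 against DMSO with the spread of these arrays, the fit recovered 42.3% of genes changed by 1.5-fold, 87.7% of those changed by 2-fold and 99.2% of those changed by 4-fold. Of the simulated calls, 5.28% were unchanged genes. The simulated noise was independent between arrays, and more genes were changed than were called in the data. With fewer changed genes the adjusted threshold is stricter, so recovery in the data may be lower.

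The genes named were, per comparison, the 10 largest rises and 8 largest falls among called genes, up to 4 called members per list, and a panel of 14 genes reported whether called or not. Other genes are named only where stated to be chosen after their values were seen. In the panel, BTG2 had 0 probes with that symbol, and the probes of FAS and GDF15 did not pass the detection filter, so these 3 genes were not analysed here. A further panel gene is not reported here. For a gene detected on 0 arrays of a group, the fold is given as a bound. It is the mean of the brighter group against the mean of, per array, the higher of the lowest detected signal and the gene's own signal. For a called gene detected on some arrays of the dimmer group, the fold with the undetected arrays held at that level is given beside the fitted fold, a step added after the results were seen.

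Repeat numbers were checked for pairing. The deviations of arrays from their group means correlated at 0.12 to 0.56 in the 12 pairs of arrays that share a repeat number, with a median of 0.39. For arrays with other numbers the median was -0.15. The numbers therefore pair the arrays, and a fit with the repeat number as a replicate block is given beside a result where it changes the call. Among the 12 arrays, 11 correlated best with an array of their own number. No 2 arrays held identical signals.

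Alternatives were other normalizations and background corrections, other filters on dim probes, every kept probe on its own, array weights, an intensity trend with a robust prior, other thresholds, fits of only the groups compared, and leaving out each array in turn. Leaving out all arrays of repeat 3 or of repeat 4, 2 lists without their p53 targets, and changes taken within repeats for the genes called with part of the RG7388 arrays, were alternatives chosen after the data were seen. Chip identifiers are not used here, so the chip could not be entered as a block. Overlap of calls against the shared DMSO arrays was set beside 100 simulations of unchanged groups and beside the overlap with the DMSO arrays split.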

Results

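NGP is a neuroblastoma cell line with amplified MYCN. RG7388 (idasanutlin) blocks the binding of MDM2 to p53, and GSK2830371 inhibits the phosphatase WIP1, the product of PPM1D, which removes activating phosphates from p53 and its kinases. The arrays measured transcripts after 4 h in 3 groups of 4 arrays. Mean signal per array ranged from 393 to 557, and between 14776 and 16228 probes were detected per array. Per group, the mean number of detected probes was 15764 ± 309 (SD, n = 4) for DMSO, 15304 ± 235 for RG7388 and 15270 ± 665 for RG7388 with GSK2830371.

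RG7388 against DMSO asked which transcripts the MDM2 inhibitor moved within 4 h. By limma, RG7388 raised 11 genes and lowered 0, and 9 of the 11 belong to the lists of p53 targets. At an unadjusted p under 0.05, 143 genes were higher and 121 lower, 264 in all where chance gives 494. The fit with the replicate block gave 569. Without the block, differences between repeats stay in the spread and lower such counts, so 494 is not a fair value for them. The largest rise was in PHLDA3, an inhibitor of AKT, from 7.43 ± 0.78 to 9.72 ± 0.02 on the log2 scale (SD, n = 4), a 4.88-fold rise. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 4.31-fold, from 10.35 ± 0.70 to 12.45 ± 0.43. Under the authors' values and without background correction CDKN1A rose more than PHLDA3. Its log2 changes were then 2.07 and 2.06, against 1.58 and 1.97 for PHLDA3. SESN1, a stress-induced regulator of mTORC1, rose 2.94-fold and RGMA, a repulsive guidance molecule, rose 2.74-fold.

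By limma, the log2 changes were 2.29 with an SE of 0.27 for PHLDA3 (adjusted p = 0.000837), 2.11 with an SE of 0.29 for CDKN1A (adjusted p = 0.00565), 1.55 with an SE of 0.17 for SESN1 (adjusted p = 0.000544) and 1.46 with an SE of 0.15 for RGMA (adjusted p = 0.000442). ACTA2, smooth muscle actin, rose 2.12-fold, DDB2, a nucleotide excision repair factor, 1.96-fold, and TNFRSF10B, a TRAIL receptor, 1.92-fold. SESN2 rose 1.80-fold, TIGAR, a regulator of glycolysis, 1.79-fold, and ZNF79, a zinc finger gene, 1.63-fold. PLK2, a polo-like kinase, was detected on 0 of 4 DMSO arrays and on 4 of 4 RG7388 arrays, a rise of at least 1.29-fold (adjusted p = 0.0485 by limma). DDB2 was detected on 1 of 4 DMSO arrays, and with the other 3 at the lowest detected signal its rise was 1.57-fold. All 11 genes were higher in 4 of 4 repeats. PHLDA3, CDKN1A, SESN1 and RGMA stayed called by limma with the authors' normalized values, without background correction and without any 1 of 8 arrays. TIGAR stayed called with the authors' values (log2 change 0.587, adjusted p = 0.0386) and without background correction, but its call ended without 7 of 8 single arrays. The other 6 genes lost their calls in both of these ways to process the signals. With the authors' values ACTA2 had a log2 change of 0.408 (adjusted p = 0.595 by limma), PLK2 of 0.233 (0.994), DDB2 of 0.229 (0.894), TNFRSF10B of 0.381 (0.264), SESN2 of 0.366 (0.155) and ZNF79 of 0.296 (0.236). Without background correction the adjusted p of these 6 was 0.0663 to 0.253, and each call ended without at least 6 of 8 single arrays. Of the 4 genes that stayed called throughout, RGMA had a log2 change of 0.662 with the authors' values, against 1.46.

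Of the panel genes not called, TP53INP1 had a log2 change of 1.33 (SE 0.28, adjusted p = 0.128 by limma) and MDM2 of 0.81 (SE 0.16, adjusted p = 0.121). PPM1D, the target of GSK2830371, had a log2 change of 0.49 (SE 0.21), and of 0.27 without DMSO replicate 4. The pro-apoptotic genes BBC3, BAX and PMAIP1 had log2 changes of 0.47 (SE 0.15), 0.28 (SE 0.17) and 0.35 (SE 0.19). The other kept BAX probe had 0.11, and BAX had 0.18 without RG7388 replicate 4. With the authors' values MDM2 had 0.38, BBC3 0.18, PMAIP1 0.15 and TP53INP1 0.77. MDM4, detected on 3 of 4 RG7388 arrays, and MYCN had log2 changes of 0.052 (SE 0.21) and -0.030 (SE 0.11). The MYCN probe ranked 5 to 36 among 47320 probes by signal on the 12 arrays, near their upper limit, where a change may not show. The other MYCN probe, ranked 337 to 493, had log2 changes of -0.061 here, -0.13 for the combination against DMSO and -0.068 for the combination against RG7388.

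**Figure D1:**
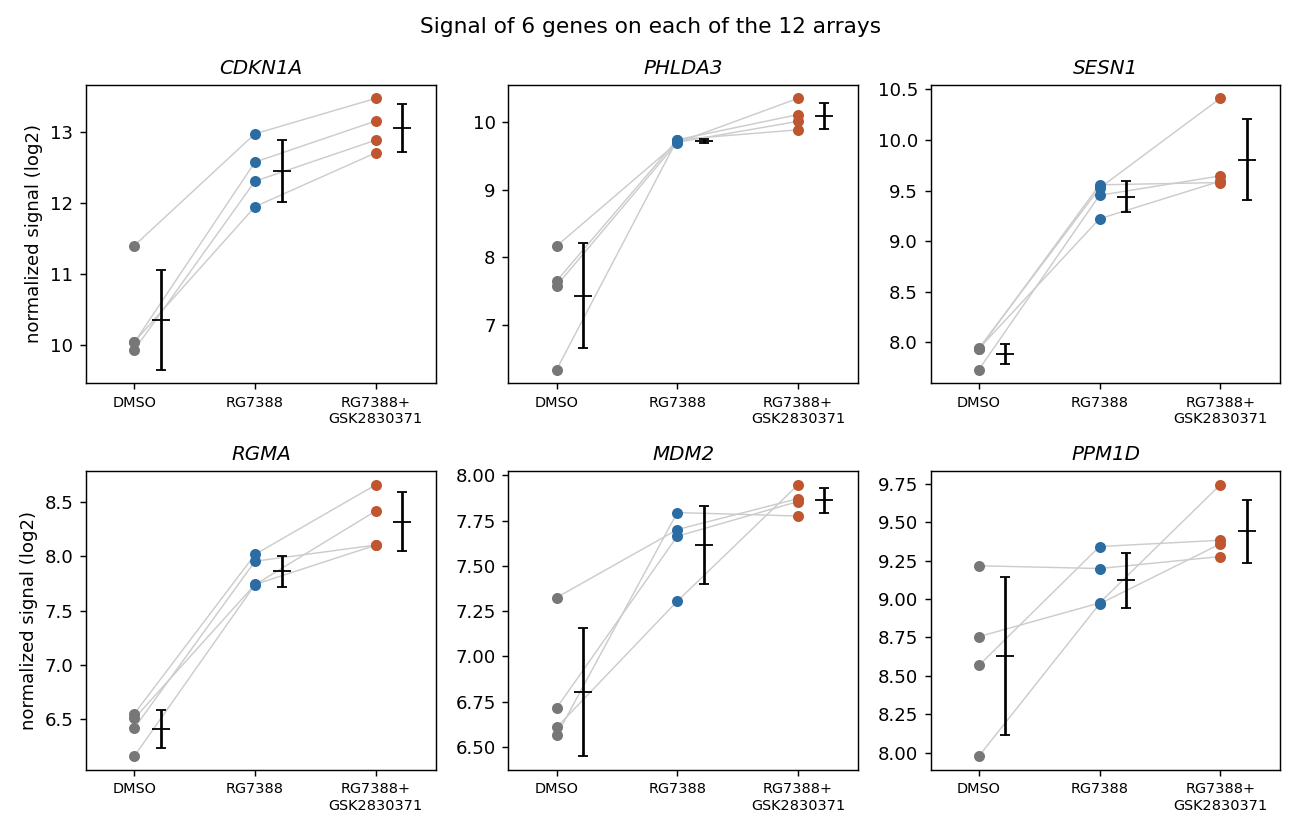
Normalized log2 signal of 6 genes (vertical axis, log2 units, each panel with its own range) on each of the 12 arrays by group (horizontal axis). Points are arrays, grey lines join arrays of one repeat, and bars give the mean and SD of 4 arrays; CDKN1A rose from 10.35 with DMSO to 12.45 with RG7388 and 13.06 with both compounds.

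All 6 lists of p53 targets moved up with RG7388. In the list of cell cycle arrest genes, 2 of 16 measured members were called, CDKN1A and PLK2, and 7 rose when adjusted over the list alone. The median log2 change was 0.406 (0.375 with PLK2 at its bound), with a camera adjusted p of 2.01e-17. In the apoptosis list 1 of 17 was called and 7 rose adjusted over the list alone, with a median of 0.35 (camera adjusted p = 8.12e-12). Among DNA repair genes 1 of 14 was called and 6 rose adjusted over the list alone, with a median of 0.32 (camera adjusted p = 1.63e-13). In the metabolism and redox list SESN1, SESN2 and TIGAR were called among 22, and 4 members rose adjusted over the list alone, with a median of 0.068 (camera adjusted p = 6.5e-08). The negative feedback list had PHLDA3 called among 10 and 2 adjusted over the list alone, and the remaining list of p53 targets had ZNF79 called among 34 and 6 adjusted over the list alone. Their medians were 0.12 and 0.14 and their camera adjusted p values 0.00011 and 3.12e-09. Of the members, 6 of 10 in the feedback list, 15 of 22 in the metabolism list and 24 of 34 in the remaining list lay above 0. Without single arrays the median was 0.057 to 0.25 for the feedback list, 0.064 to 0.18 for the metabolism list and 0.13 to 0.22 for the remaining list. With the authors' values the 6 medians were 0.033 to 0.213. With no filter on detection the medians of the apoptosis, feedback and remaining lists were 0.12, 0.045 and 0.074. The calls of all 6 lists held with an estimated correlation, at adjusted p = 0.00012 to 0.0235.

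Of the lists that were not called, G1/S and E2F targets had a median log2 change of -0.0090, G2/M genes of 0.023, MYC and MYCN targets of -0.0056 and adrenergic identity genes of -0.014. Immediate early genes had a median of 0.049 and the ATF4 list of -0.0052 with a mean of 0.033. NF-kB targets had a median of -0.079, heat shock genes of 0.055, hypoxia genes of 0.024, cholesterol synthesis genes of 0.029 and ribosomal proteins of 0.022. Interferon response and xenobiotic response genes had medians of -0.013 and -0.0084 and means of 0.070 and 0.012. Markers of other cell types were scarce, with 3 of 14 leukocyte and 2 of 13 epithelial markers measured, medians of -0.023 and 0.075, and 0 called. The list of mesenchymal identity genes had a median of -0.20 and 2 of 13 members above 0 (camera adjusted p = 0.054). With the replicate block it passed, at a camera adjusted p of 0.00221, and at an adjusted p = 0.0363 with an estimated correlation. By limma with the replicate block 18 genes were called, all of them higher, among them all 11 above, TP53INP1 (adjusted p = 8.4e-06) and MDM2 (adjusted p = 0.0151). INKA2, AEN, BLOC1S2 and TRIAP1, named here after their values were seen, were also among the 18. Their log2 changes were 1.22, 0.82, 0.72 and 0.64 (adjusted p = 4.01e-06, 0.0151, 0.00795 and 0.0413 by limma with the block). Without the block their adjusted p was 0.0545 to 0.174. Other kept probes had 0.46 and 0.85 for INKA2, 0.88 for AEN and 0.16 for BLOC1S2. Without any 1 of the 4 DMSO or 4 RG7388 arrays, the number of called genes was 4 to 7: 6, 5, 4 and 7 without DMSO replicates 1 to 4, and 4, 4, 4 and 6 without RG7388 replicates 1 to 4.

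RG7388+GSK2830371 against DMSO asked what both compounds moved together. By limma, the combination raised 21 genes and lowered 0, and 18 of the 21 belong to the lists of p53 targets. At an unadjusted p under 0.05, 194 genes were higher and 175 lower, 369 in all where chance gives 494, and 710 with the replicate block. The count without the block is again lowered by differences between repeats. CDKN1A rose 6.56-fold, to 13.06 ± 0.33 (SD, n = 4), and PHLDA3 6.32-fold, to 10.09 ± 0.20. SESN1 rose 3.79-fold, RGMA 3.77-fold, INKA2, an inhibitor of the kinase PAK4, 3.59-fold, and ACTA2 3.22-fold. TP53INP1, a stress-induced p53 cofactor, rose 2.96-fold and MDM2, the ubiquitin ligase that p53 induces against itself, 2.09-fold.

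By limma, the log2 changes were 2.71 with an SE of 0.29 for CDKN1A (adjusted p = 0.000214), 2.66 with an SE of 0.27 for PHLDA3 (adjusted p = 0.00011), 1.92 with an SE of 0.17 for SESN1 (adjusted p = 2.9e-05) and 1.91 with an SE of 0.15 for RGMA (adjusted p = 9.32e-06). INKA2 had a log2 change of 1.84 (SE 0.26, adjusted p = 0.00239), and its other kept probes had changes of 0.68 and 1.27. SESN2 rose 2.38-fold and TNFRSF10B 2.32-fold. EDA2R, a death receptor family member detected on 1 of 4 DMSO arrays, rose 2.14-fold and DDB2 2.27-fold. With the 3 DMSO arrays where they were not detected at the lowest detected signal, EDA2R rose 1.55-fold and DDB2 1.82-fold. PLK2, detected on 0 of 4 DMSO arrays and 3 of 4 combination arrays, rose at least 1.58-fold (adjusted p = 0.00285). TIGAR rose 2.08-fold, ZNF79 1.97-fold, BLOC1S2 1.83-fold, PLCL2 1.80-fold, AEN, an apoptosis-enhancing nuclease, 1.74-fold, TRIAP1 1.65-fold and TOB1, an antiproliferative gene, 1.61-fold. The other kept probe of BLOC1S2 had a log2 change of 0.24 and was not called. UBASH3B, in none of the p53 lists, rose 2.18-fold, or 2.02-fold with its 3 undetected DMSO arrays at the lowest detected signal; it is named here after its values were seen. With the authors' normalized values INKA2, TP53INP1, EDA2R, DDB2, PLK2, BLOC1S2, PLCL2, AEN and UBASH3B were not called by limma (adjusted p = 0.0598 to 0.469). EDA2R was also not called without background correction (adjusted p = 0.124). The call of TOB1 ended without each of 8 single arrays, those of EDA2R, AEN and PLCL2 without 7, those of BLOC1S2, TRIAP1 and UBASH3B without 6 and that of TP53INP1 without 4. For 14 of the 21 genes the log2 change was over 1.5 times smaller with the authors' values, up to 4.34 times.

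PPM1D had a log2 change of 0.81 (SE 0.21, adjusted p = 0.35 by limma), and BBC3 of 0.68 (SE 0.15, adjusted p = 0.125). With the replicate block both were called, at adjusted p = 0.0422 and 0.0162. The other kept BAX probe had a log2 change of 0.19, where BAX had 0.48 (SE 0.17). PMAIP1 had 0.32 (SE 0.19), with 0.15 to 0.49 without single arrays and 0.14 with the authors' values, under which BBC3 had 0.27. MDM4 and MYCN had 0.099 (SE 0.21) and -0.00096 (SE 0.11). MDM4 was detected on 3 of 4 combination arrays.

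All 6 lists of p53 targets moved up with the combination. In the cell cycle arrest list 3 of 16 were called and 9 rose adjusted over the list alone, with a median log2 change of 0.58 (camera adjusted p = 1.77e-19). In the apoptosis list 4 of 17 were called, TNFRSF10B, TP53INP1, EDA2R and AEN, and 9 rose adjusted over the list alone, with a median of 0.48 and 17 of 17 above 0 (camera adjusted p = 5.25e-19). Among DNA repair genes 2 of 14 were called and 8 rose adjusted over the list alone, with a median of 0.57 (0.46 with 1 member, detected on 0 DMSO arrays, at its bound; camera adjusted p = 2.22e-15). The metabolism list had 4 of 22 called and 7 adjusted over the list alone, the feedback list 2 of 10 and 3, and the remaining list 4 of 34 and 8. Their medians were 0.19, 0.11 and 0.18 and their camera adjusted p values 8.62e-11, 4.97e-05 and 2.23e-12. Of the members, 6 of 10 in the feedback list, 16 of 22 in the metabolism list and 27 of 34 in the remaining list lay above 0. Without single arrays the median of the feedback list was 0.045 to 0.29 and that of the metabolism list 0.13 to 0.27. With the authors' values the 6 medians were 0.0705 to 0.351. With no filter on detection the medians of the cell cycle arrest, apoptosis, metabolism and remaining lists were 0.36, 0.13, 0.11 and 0.046. With an estimated correlation the adjusted p of the 6 lists was 7.5e-05 to 0.00866.

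Immediate early genes and the ATF4 and unfolded protein response list also moved up, at camera adjusted p = 0.0163 and 0.0393, with medians of 0.098 and 0.077. With an estimated correlation the adjusted p = 0.217 and 0.734, so neither call held without the replicate block. With the block the camera adjusted p was 0.0017 and 0.00903. With the block and an estimated correlation the immediate early call held at an adjusted p = 0.0285, and the ATF4 call ended at 0.109. The block fit called ARC (log2 change 0.74, adjusted p = 0.00712 by limma), named after its values were seen, and adjusted over the list alone 4 immediate early genes rose and 1 fell. Without the block, adjusted over the list alone, 0 of 21 immediate early genes and 1 of 24 ATF4 list genes rose. The 1 gene was SESN2, which is also a p53 target. The ATF4 call also ended without DMSO replicate 3 or 4 (adjusted p = 0.717 and 0.0549) and without RG7388+GSK2830371 replicate 2 or 4 (0.457 and 0.182), and its median turned negative without DMSO replicate 3 (-0.0095) or RG7388+GSK2830371 replicate 2 (-0.019). The median of the immediate early genes was 0.063 to 0.20 without single arrays, and 0.056 with the authors' values, where that of the ATF4 list was 0.039. The immediate early call ended without DMSO replicate 3 (0.257) and without RG7388+GSK2830371 replicate 1 or 2 (0.114 and 0.0687). The remaining lists were not called, with medians of -0.058 for G1/S and E2F targets, 0.019 for G2/M genes, 0.015 for MYC and MYCN targets and -0.043 for adrenergic identity genes. The medians were -0.057 and -0.11 for leukocyte and epithelial markers, -0.087 for NF-kB targets, 0.042 for interferon response genes, 0.022 for heat shock genes and 0.056 for cholesterol synthesis genes. Ribosomal proteins had a median of -0.0033. Hypoxia genes had a median of 0.046 with camera's direction down, and xenobiotic response genes a median of -0.0027 with camera's direction up. The mesenchymal list had a median of -0.15 (camera adjusted p = 0.26), and passed with the replicate block at 0.0376, with an adjusted p = 0.109 with an estimated correlation. By limma with the replicate block 38 genes were called, 35 higher and 3 lower, among them all 21 above. The 3 lower genes, named after their values were seen, were TELO2, SLC35D3 and RGS4, at log2 changes of -1.11, -0.75 and -0.62. Without DMSO replicate 1, or without RG7388+GSK2830371 replicate 3, 13 genes were called.

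RG7388+GSK2830371 against RG7388 asked what the WIP1 inhibitor added to the MDM2 inhibitor. Of 9882 genes, limma called 0, and 162 had an unadjusted p under 0.05 where chance gives 494. The fit with the replicate block called 0 as well, with 399 at an unadjusted p under 0.05. Differences between repeats lower the count without the block, so 494 is not a fair value for 162. The count with the block, 399, also lay below 494, and the cause of that was not tested. Among the 21 genes called with the combination against DMSO, 20 had a log2 difference above 0 and 7 had an unadjusted p under 0.05. None passed the adjusted threshold. The median added log2 change of the 21 genes was 0.27. These genes were picked for high values on the same combination arrays. That choice pushes the share above 0 and the median up, and no value without change was computed for this set.

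CDKN1A had an added log2 change of 0.61 (SE 0.29, 95% confidence interval -0.015 to 1.23), higher in 4 of 4 repeats. The SEs and intervals given here come from the fit without the replicate block, which leaves differences between repeats in the spread. The block gave smaller SEs of 0.153 for CDKN1A, 0.114 for INKA2 and 0.132 for TP53INP1, a slightly larger one of 0.113 for MYCN, and 0 calls. ACTA2 had 0.61 (SE 0.19, unadjusted p = 0.00522 by limma), INKA2 0.62 (SE 0.26), RGMA 0.46 (SE 0.15), SESN2 0.40 (SE 0.14) and SESN1 0.37 (SE 0.17), which was 0.17 without RG7388+GSK2830371 replicate 3. The other kept INKA2 probes had 0.22 and 0.42. With the authors' values ACTA2 had 0.30, INKA2 0.36, RGMA 0.30 and SESN2 0.21. These genes, among the larger added changes, are named here after their values were seen, as are the smaller ones that follow. AEN had -0.026, TRIAP1 0.088, BLOC1S2 0.15, TOB1 0.17, PLCL2 0.20, and TIGAR and DDB2 0.21. MDM2 had 0.25 (SE 0.16, interval -0.10 to 0.60), with 0.14 without RG7388 replicate 3 and 0.13 with the authors' values, and PPM1D 0.32 (SE 0.21, interval -0.12 to 0.76). BBC3, BAX and TP53INP1 had 0.21 (SE 0.15), 0.20 (SE 0.17) and 0.23 (SE 0.28). BBC3 had 0.088 with the authors' values. Other kept probes gave 0.080 for BAX and 0.41 for TP53INP1, and without single arrays BAX had 0.073 to 0.30 and TP53INP1 0.072 to 0.40. PMAIP1, MDM4 and MYCN had -0.024 (SE 0.19), 0.047 (SE 0.21) and 0.029 (SE 0.11).

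Of the 22 lists, the apoptosis and death receptor list moved up, with 14 of 17 members above 0 and a median log2 change of 0.20 (camera adjusted p = 0.00158). Adjusted over the list alone, 0 of its members were called. With an estimated correlation the adjusted p = 0.221, and with fry it was 0.444. The median was 0.095 with the authors' values and 0.11 with no filter on detection. Within repeats the list's mean change was 0.18, 0.23, 0.18 and 0.13 (mean 0.18 ± 0.04, SD, n = 4), with an exact sign-flip p of 0.125, the smallest that 4 repeats allow. The metabolism and cell cycle arrest lists had medians of 0.067 and 0.12 (camera adjusted p = 0.0511 and 0.106), the DNA repair list 0.092 (0.171), the feedback list 0.013 (0.459) and the remaining p53 targets 0.089 (0.0795). The ATF4 list had a median of 0.085 (0.0649). The other 15 lists had medians from -0.185, for 2 epithelial markers, to 0.0492, for immediate early genes, and camera adjusted p from 0.459 to 0.913. By camera with the replicate block 5 lists were called, all higher, which were the apoptosis list (adjusted p = 0.000105), the cell cycle arrest, metabolism and remaining p53 lists (0.0228, 0.0215 and 0.0215) and the ATF4 list (0.0215). With the block and an estimated correlation, the adjusted p of these 5 was 0.174 to 0.184.

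**Figure D2:**
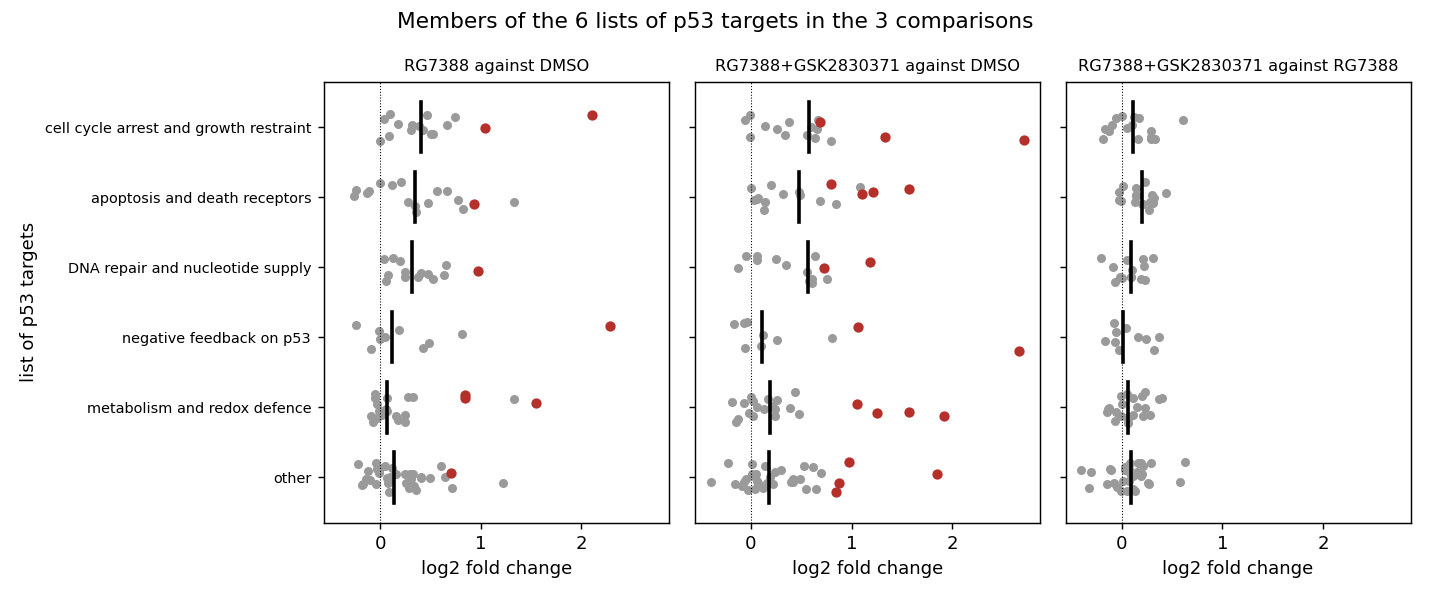
Log2 fold change (horizontal axis) of the measured members of the 6 lists of p53 targets (vertical axis) in the 3 comparisons. Points are genes, red where called at an adjusted p under 0.05, with random vertical spread, and black bars are list medians; the medians of the apoptosis list were 0.35, 0.48 and 0.20.

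The genes called with RG7388 were also called with the combination. All 11 were shared and had the same direction. Independent lists of 11 and 21 genes among 9882 would share 0.0234, and unchanged groups simulated against the shared DMSO arrays shared 0 on average. Unchanged groups yield few calls at this threshold, and both treatments contain RG7388. Neither value therefore tests how far the shared DMSO arrays raise the overlap. With the DMSO arrays split between both comparisons, 3 to 4 genes were shared, with a mean of 3.5 over 6 splits, and the smaller groups also called fewer genes. With the replicate block 18 were shared. Across genes, which are not independent replicates, log2 changes correlated at 0.66, and unchanged simulated groups gave 0.50. The covariance was 0.018 and 0.0178 in the simulation. With the DMSO arrays split the mean covariance was -0.00116.

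The genes called with 2 of the 4 RG7388 arrays were followed when GSK2830371 was added. In each of 6 splits of the RG7388 arrays, the genes called against DMSO with 2 arrays were followed from the other 2 arrays to the combination. Between 3 and 5 genes were called per split, and 100% were higher in the combination. Differences between repeats enter both sides of this comparison with the same sign, so this share has no value without change to stand against. In a form added after the results were seen, both changes were taken within repeats and from separate repeats. There 3 of 6 divisions called any gene, 5 calls in all, and all 5 were higher in the combination. Of the genes outside the p53 lists, 48.6% to 54.5% had the same sign in both changes. With all 4 RG7388 arrays on both sides, where array noise acts against it, all 11 called genes were also higher in the combination, by 0.21 to 0.61. Unchanged groups simulated in this form had the same sign for 33.4% of genes. That share is over all genes, and the 11 called genes are not independent replicates, so it does not test them.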

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

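In 78 groups of 4 arrays, taken over the named genes, 4 held a value far from the other 3, where chance gives about 3.9. CDKN1A was 11.4 on the log2 scale with DMSO in replicate 4, and 9.927 to 10.04 on the other DMSO arrays. SESN1 was 7.731 with DMSO in replicate 1 (7.931 to 7.941 on the others) and 10.41 with RG7388+GSK2830371 in replicate 3 (9.579 to 9.644 on the others). TOB1 was 9.022 with RG7388+GSK2830371 in replicate 2 (9.228 to 9.267 on the others).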

How the results depend on the processing

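Leaving out repeat 3 or repeat 4, and taking the added change of called genes within separate repeats, were chosen after the data were seen. With RG7388 against DMSO, 11 genes were called. The count was 5 with the authors' normalized values, 6 without background correction, 6 with normexp without control probes, 4 with median scaling only, 5 with no filter on detection, 18 with the replicate block, 6 from only the groups compared, 4 at an adjusted p under 0.01, 3 without repeat 3 and 7 without repeat 4. Without single arrays it was 4 to 7. With RG7388+GSK2830371 against DMSO, 21 genes were called, against 12 with the authors' values, 10 with median scaling only, 38 with the replicate block, 13 at an adjusted p under 0.01, 11 without repeat 3 and 13 to 21 without single arrays. With RG7388+GSK2830371 against RG7388 the count was 0 under every alternative run. The 6 p53 lists kept their direction and call in both comparisons with DMSO under every alternative run on lists. For RG7388+GSK2830371 against RG7388, 1 list was called, against 0 with an estimated correlation, 0 with fry, 5 with the replicate block, 3 with the authors' values, 3 without repeat 3, 2 without repeat 4 and 1 to 6 without single arrays. The overlap of 11 genes was 5 with the authors' values, 5 with no filter on detection, 18 with the replicate block, 3.5 with the DMSO arrays split and 4 to 11 without single arrays.

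A stricter threshold cannot give more calls, and fewer arrays mostly gave fewer called genes, but not always. Without DMSO replicate 4 the combination against DMSO still had 21 called genes. Without RG7388 replicate 2 the number of lists called with RG7388 against DMSO rose from 6 to 8. For the other alternatives the cause was not tested. Single genes that changed sign had values near 0 and were not called. The median of the ATF4 list, called with RG7388+GSK2830371 against DMSO, turned negative without DMSO replicate 3 (-0.0095) or RG7388+GSK2830371 replicate 2 (-0.019), where its call also ended. MYCN, near the upper limit of the signal, was -0.0679 with its other probe in RG7388+GSK2830371 against RG7388. Without single arrays, MDM4 was -0.0836 to 0.245 with RG7388 against DMSO, -0.0183 to 0.262 with the combination against DMSO and -0.146 to 0.21 between them. MYCN was -0.0516 to 0.00526, -0.0209 to 0.0122 and -0.00622 to 0.0506 in the same order, and PMAIP1 -0.195 to 0.146 between the treatments. Genes near background, such as PLK2, are limited by signal over background. The chip as a block was not run.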

Other observations

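The tests of repeats 3 and 4 left out, of lists without their p53 targets, of the apoptosis list against the other p53 targets, of the slope of the added change and of splits that part every repeat without the block were chosen after the results were seen. Gene expression differed between the 4 repeats beyond the treatments. By limma, 1384 of 9882 genes (14%) differed between repeats after group means were taken off. The genes named here were chosen after their values were seen. GATA2, a transcription factor of adrenergic cells, lay at 0.59, 0.38, 0.92 and -1.88 log2 from its group means in repeats 1, 2, 3 and 4 (SD 0.056 to 0.22, 3 arrays each). The metallothionein MT1G lay at -1.54, -1.36, 0.55 and 2.35, and the heat shock gene HSPA6 at 0.011, -0.17, -1.92 and 2.07. HMGCS1, an enzyme of cholesterol synthesis, lay at -0.76, -0.35, 0.49 and 0.61.

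Of the adrenergic identity genes, 16 of 28 differed between repeats (Fisher's exact adjusted p = 2.55e-06 over 22 lists), as did 10 of 17 cholesterol synthesis genes (adjusted p = 0.000235), 9 of 16 heat shock genes (0.000669), 11 of 24 ATF4 list genes (0.000924) and 9 of 21 immediate early genes (0.00532). The mesenchymal list (6 of 13), the remaining p53 targets (11 of 34) and xenobiotic response genes (5 of 12) also passed. Fisher's test counts genes as independent, and genes of a list can move together across repeats, so these p-values may be too small. Under 4 other scalings at least 954 genes differed, so the scaling of the arrays alone does not account for the differences. The MYCN probe with the most signal lay at most 0.309 log2 below the array maximum, so its repeat means, within 0.0636 log2, decide nothing. The other MYCN probe, 1.27 to 1.9 log2 below the maximum and taken up after the results were seen, had repeat means within 0.124 log2. This argues against a whole repeat grown from a line without MYCN amplification, not against a smaller share of such cells. The labels give no further difference between repeats, and other explanations from biology were not tested. Technical differences between repeats, such as the chip, were not tested either, because chip identifiers are not used here. Other scalings cannot exclude them.

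The apoptosis list had a median change of 0.20 with GSK2830371 added to RG7388. Its call did not hold, at an adjusted p = 0.221 with an estimated correlation, 0.174 with the replicate block as well and 0.444 with fry, and adjusted over the list alone 0 members were called. The lowest median was 0.0946 over 4 other scalings and 0.155 without any 1 of the 8 arrays, and 4 of 4 repeats lay above 0. The direction of the change therefore did not rest on 1 scaling, 1 array or 1 repeat. Its size did depend on the scaling, since all 4 other scalings gave smaller medians, 0.0946 to 0.153. Because the call did not hold, these values cannot exclude the scaling or differences between arrays or repeats as a cause. Whether this list moved more than the other p53 targets cannot be told apart from a larger response of them all. The difference of medians, 0.11, had a two-sided permutation p of 0.0399, and of up to 0.268 under 4 other scalings. The permutation counts genes as independent, and genes of a list can move together, so these p-values may be too small. A stronger p53 response when WIP1 is inhibited may underlie a rise, if there is one, but an array of GSK2830371 alone was not analysed here.

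The ATF4 and unfolded protein response list was called higher with RG7388+GSK2830371 against DMSO. The adjusted p = 0.734 with an estimated correlation and 0.696 with fry, and the median, 0.077, fell to -0.0095 without DMSO replicate 3 and -0.019 without RG7388+GSK2830371 replicate 2. Without its 2 p53 targets, SESN2 and ATF3, the camera p of the other 22 genes was 0.308, so the p53 targets could account for its call. For immediate early genes without ATF3, the median was 0.0975 against 0.0984 with it, and the camera p was 0.0176. The adjusted p moved from 0.0163 to 0.0554, so the call ended with little change in the median. ARC, chosen after its values were seen, had the largest log2 change of that list, 0.74.

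A hypothesis is that GSK2830371 adds to each p53 target in proportion to its RG7388 response. Both changes were taken within repeats, and from separate repeats. Across 110 p53 list members, the slope of the added change on the RG7388 change was 0.22 on average and 0.171 to 0.258 over 6 divisions of the repeats. For 9772 genes outside the lists it was -0.0268 to 0.136. The correlation across p53 list members, which are not independent replicates, was 0.39 to 0.49. A first form of the test did not match repeats, and gave 0.266 for p53 list members and 0.236 for the genes outside, since repeat differences entered both changes. The positive slope means that members with a larger RG7388 change had a larger added change on average. It does not show that each target gained in proportion. AEN and INKA2, chosen after their values were seen, had RG7388 log2 changes of 0.82 and 1.22 and added changes of -0.026 and 0.62. The hypothesis was found and tested on the same arrays. No array of GSK2830371 alone was analysed here, so an effect of it without RG7388 cannot be told apart.

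The groups were compared with the other ways to split their 8 arrays 4 against 4. Since repeat numbers pair the arrays, only the 8 splits that part every repeat compare like with like, and 8 are too few for a share under 0.05. The other 27 put both arrays of at least 1 repeat into 1 group, so differences between repeats enter them. For RG7388 against DMSO, 1 of 35 splits, the real one, called 11 genes and the highest other called 2. That other split set repeats 1 and 2 against 3 and 4. For RG7388+GSK2830371 against DMSO, 1 of 35 called 21 genes and the highest other called 0. For RG7388+GSK2830371 against RG7388, 35 of 35 called at least the real 0, with 1 as the highest other. Among the 8 splits the highest other called 0 genes in each comparison.

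For the number of lists, 12 of 35 splits called at least the 6 lists of RG7388 against DMSO (highest other 11), 7 at least the 8 lists of the combination against DMSO (highest other 12) and 25 at least the 1 list of the combination against RG7388 (highest other 8). The splits with the highest counts put both arrays of at least 1 repeat into 1 group, which points to the repeats as a structure of the samples. The splits with 11 and 12 lists also kept most treated arrays in 1 group, and so part of the treatment difference. Among the 8 splits that part every repeat, the highest other called 5, 6 and 0 lists. The 5 and 6 came from splits with most treated arrays still in 1 group, which keep part of the treatment difference. In both comparisons with DMSO, those of the 8 with equal numbers of treated and DMSO arrays per group called 0 lists. With the replicate block, the real counts over these 8 splits were 18, 38 and 0 genes, with 0 as the highest other in each comparison, and 7, 9 and 5 lists, with 5, 7 and 0 as the highest other. As many as the real count came from 1, 1 and 8 splits for genes and from 1, 1 and 1 for lists.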
